A study of Homo sapiens with 12 samples.

How the data were processed

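Total RNA of 12 samples of 2 kinds, human embryonic stem cells (hESC) and neural stem cells made from them (NSC), was hybridised to Illumina single-colour BeadChip arrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase I treatment, checked on a Bioanalyser and turned into biotinylated cRNA. The array scans were summarised with GenomeStudio 2010.2.0.25786, per the submitters' processing notes. Samples were grouped by their titles, which give 6 hESC and 6 NSC replicates. The labels do not say whether the replicates of a group are separate cultures, so the p-values measure the spread between these samples, which may be technical.

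The deposited non-normalized table gives, per the file headers, an intensity and a detection value for each of 47225 probes on each array. The intensity is on a linear scale. The deposited detection p-value ranks a probe against the negative controls of its array, and its steps correspond to 770 controls. A second table by the authors holds intensity values that share one distribution across the 12 arrays, with a rank correlation of 1 with each array's own non-normalized values. Those are quantile-normalized intensities on a linear scale, to judge from the values, with column medians between 144.87 and 144.95. Any background step before these tables is not given in the sources used here. No control probe intensities, slide numbers or scan dates were used here.

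From the non-normalized intensities, the background was corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the negative controls' mean and spread inferred from the detection p-values and an offset of 16. The arrays were then quantile normalized and put on a log2 scale. Probe names came from the platform's gene table, updated through gene identifiers to the symbols of the GRCh38.p14 annotation. A single gene was named for 30111 probes (30072 through the gene identifier, 18 through an accession, 21 by the platform table alone), several genes for 8 probes and none for 17106. Probes with several genes or none were left out of the gene tests. A probe entered when its detection p-value was below 0.01 on at least 6 arrays, which 18853 probes met, 15223 of them with a single gene. Of several probes of a gene, the one with the highest mean log2 intensity over all arrays stood for it, which gave 11492 genes. Several tested probes existed for 3022 genes, and for 70 genes they were called in opposite directions.

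Differences are log2 intensities of NSC minus hESC, from limma's linear model with group as the only term and empirical Bayes variances. They were tested two-sided and adjusted by Benjamini-Hochberg over the 11492 genes. The verbs rose and fell mean higher and lower in NSC at an adjusted p below 0.05. Where the probe that stands for a gene was above background on no array of one group, the fold is a lower bound, written as at least N-fold, with each array of that group at no less than its lowest detected signal. The bound is on the background-corrected scale, and it can exceed the fold fitted without that correction. For 4 genes detected on 1 array of a group, the fold computed that way is given too. It sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest signal of a detected probe. Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes and adjusted over the 26 lists with at least 5 genes tested. Camera with an estimated correlation and limma's fry were run beside it. The 31 lists hold 704 genes, of which 452 were tested, and 42 had no named probe and were not analysed here.

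The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and falls among genes detected on all 12 arrays whose groups did not overlap, and the 5 largest bounds in each direction among genes below background in one group and detected on all arrays of the other. It also took 10 stem cell and neural genes in any case, and from each list the largest rise and the largest fall past the threshold, or the smallest p where none passed. Genes that make up a small count and fall outside the rule were named after their values were seen, as were the leading genes of NSC replicate 5.

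The alternatives were no background correction, median scaling or cyclic loess in place of quantile normalization, the authors' table, 3 other detection filters, the mean of a gene's probes, each probe on its own, a replicate block, array weights, another variance model, a test against a 2-fold change, other set tests, and each array left out in turn. Matched random lists (10000 per test) were drawn from genes of like mean intensity. The gene test was tested on simulated data for 6 against 6 arrays and 11492 genes. It recovered 38% of changes of 0.5 on the log2 scale, 88% of changes of 1, and 100% of changes of 2 and of 4, with 12 false calls among 175. In a second simulation, camera called 1 list, the one that had been shifted by 0.5. Both simulations drew genes independently of each other, so they do not show how camera behaves with correlated genes. The first changed only 50 genes at each size, far fewer than were called in the data, so its recovery need not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.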

Results

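Transcript levels were compared between human embryonic stem cells (hESC) of the WA-09 line, an established pluripotent line, and neural stem cells (NSC) that had been derived from that line. The labels describe the NSC as an early kind of neural precursor. Each group had 6 arrays, and each array carried 47225 probes. Between 17793 and 19772 probes per array were above background (37.7% to 41.9%), and the median raw intensity of an array lay between 132.4 and 153.9. After filtering, 11492 genes were tested. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.14 (n = 6 per group).

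The groups separated on the first principal component, which held 78.3% of the variance over the genes tested. Across genes, which are not independent replicates, the correlation of log2 intensities averaged 0.988 between hESC arrays, 0.978 between NSC arrays and 0.885 between an hESC and an NSC array. NSC replicate 5 stood apart from the other NSC arrays. It lay at -58.96 on the second component (10.2% of the variance), where the other NSC arrays lay between 5.18 and 19.03, and its correlation with them averaged 0.952. Without it, NSC pairs averaged 0.991.

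**Figure D1:**
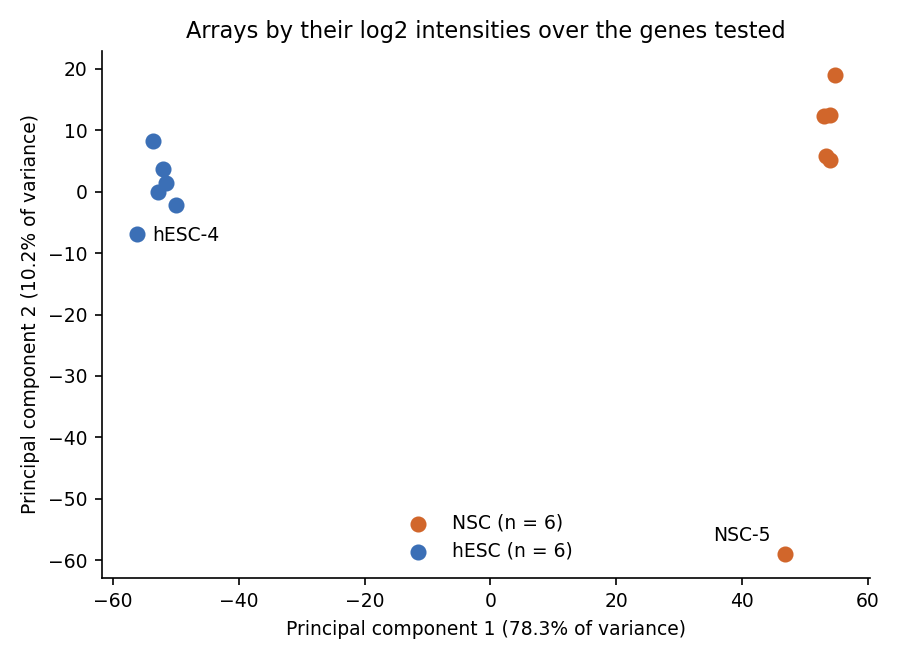
Each point is 1 array, placed by its scores on the first (horizontal) and second (vertical) principal components of log2 intensity over the genes tested, with 6 hESC arrays in blue and 6 NSC arrays in orange. The first component (78.3% of the variance) separates the groups, and the second (10.2%) sets NSC replicate 5, at -58.96, apart from the rest.

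The comparison of NSC with hESC shows which transcripts differed between these samples of the WA-09 line and of the neural precursors made from it. Any difference in culture conditions or slide between the groups cannot be told apart from cell type. The pluripotency genes POU5F1 and NANOG were far lower in NSC, and the neural patterning genes PAX6 and LHX2 far higher. POU5F1, a transcription factor at the centre of the pluripotency network, was 43.7-fold lower in NSC (log2 difference -5.45 ± 0.10 SE, n = 6 per group, limma adjusted p = 3.16e-15). NANOG, another such factor, was above background on all 6 hESC arrays and on none of the NSC arrays, and was at least 60.5-fold lower in NSC (limma adjusted p = 2.57e-16). PAX6, an early neural transcription factor, and LHX2, a factor of the forebrain and eye field, were above background on all 6 NSC arrays and on none of the hESC arrays. They were at least 64.3-fold and at least 93.1-fold higher in NSC (limma adjusted p = 2.57e-16 and 4.21e-14). These bounds hold with background correction, and without it the fitted folds were 36.6 for NANOG, 37.9 for PAX6 and 50.7 for LHX2.

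Probes of one gene did not always give the same size of change. A second POU5F1 probe, detected on 3 of the 12 arrays, differed by -0.62 ± 0.12 (SE), and a second NANOG probe, detected on 6, by -1.76 ± 0.18 (SE). As the mean of its detected probes, NANOG was 21.8-fold lower in NSC by fitted change. POU5F1 and NANOG have closely related pseudogenes, so their probes can also bind other transcripts.

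In all, 3516 genes rose and 3390 fell, together 60.1% of the genes tested. By fitted change, 994 rose and 1152 fell at least 2-fold, 2146 in sum. The arrays of the 2 groups did not overlap at all for 4340 genes, 37.8% of those tested, where chance gives 0.216%. Of the genes called, 145 were not above background on any hESC array and detected on all NSC arrays, and 173 the reverse. The 2-fold count was 1306 without background correction, 1313 in the authors' table, 1359 among genes detected on all arrays and 1159 in limma's test against a 2-fold change. Without background correction, the folds of 40 of 82 named genes were over 1.5 times smaller, such as 137-fold for DLK1 and 41.8-fold for HES5.

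Among genes detected on all 12 arrays, the largest rise was that of DLK1, an imprinted gene for a Notch-related membrane protein, which was 221-fold higher in NSC (log2 difference 7.79 ± 0.12 SE, n = 6 per group, limma adjusted p = 2.57e-16). WLS, which carries WNT proteins to the cell surface, rose 74.4-fold, and FRZB, a secreted WNT antagonist, rose 39.7-fold. PAMR1 rose 40.3-fold (11.7-fold as the mean of its detected probes), IGFBP5, which binds insulin-like growth factors, 35.1-fold, SKIDA1 25.5-fold, the protease gene PRSS23 25.5-fold and the receptor gene CNTFR 21.8-fold. After POU5F1, the largest falls were those of GAL, the gene of the neuropeptide galanin (41.9-fold), and PMAIP1, a gene for a BH3-only cell death protein (41.7-fold). SPRY4, a feedback inhibitor of FGF signalling, fell 26.8-fold, RARRES2 21.3-fold, the Notch target HEY2 20.4-fold, the long noncoding RNA UCA1 20.1-fold and the tetraspanin gene CD9 17.9-fold. The limma adjusted p of these genes lay between 2.57e-16 for DLK1 and 2.07e-09 for SPRY4. That their groups did not overlap was a condition of the rule that picked them, not a result.

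Beside PAX6 and LHX2, the largest bounds on the NSC side were those of DKK1, a secreted WNT inhibitor (at least 38.1-fold higher), LMO1 (at least 32.8-fold) and ZNF503 (at least 30.2-fold). On the hESC side, NANOG was followed by CFAP95 (at least 34.4-fold lower), HSD11B2 (at least 8.96-fold), and GDF3 and LEFTY2, both TGF-beta family ligands (at least 7.54-fold and 7.29-fold). Without background correction the fitted folds of these genes lay below the bounds, such as 18.8 for DKK1, 15.3 for CFAP95 and 5.04 for HSD11B2. DKK1 had the widest spread of these, with an SD of 1.29 on the log2 scale between NSC arrays, since NSC replicate 5 lay at 8.64 and the others between 11.56 and 12.01.

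Of 23 pluripotency factors measured, 19 fell and 3 rose (4 adjusted over the list alone), with a median log2 difference of -2.73, or -2.69 with genes below background at their bounds (camera adjusted p = 7.18e-10, and adjusted p = 0.000748 with an estimated correlation). LEFTY1, a NODAL antagonist, was detected on 1 of the 6 NSC arrays, and its fitted fall of 62.5-fold was 39.4-fold with each array at no less than its lowest detected signal, and 19-fold without background correction. DNMT3B, a de novo DNA methyltransferase, fell 5.10-fold (log2 difference -2.35 ± 0.20 SE, limma adjusted p = 7.43e-08). The 3 that rose were SOX2 (1.08 ± 0.13 SE on the log2 scale), which neural stem cells also express, SALL4 (0.94) and LIN28B (0.24). The RNA-binding factor LIN28A was bright in both, with mean log2 intensities of 14.95 in NSC and 14.75 in hESC. Its difference of 0.20 ± 0.09 (SE) missed the threshold (limma adjusted p = 0.0669), and passed it without NSC replicate 5 (adjusted p = 0.0382), without NSC replicate 6 (0.0356), without background correction (0.0392) and under 4 other alternatives (0.0117 to 0.0389).

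Genes of epithelial junctions and keratins were lower in NSC, with 18 of 21 measured falling and 1 rising (median -1.41, camera adjusted p = 6.61e-06, but adjusted p = 0.229 with an estimated correlation). The tight junction gene CLDN7 fell 7.69-fold and the E-cadherin gene CDH1 3.17-fold (log2 difference -1.67 ± 0.24 SE, limma adjusted p = 2.59e-05), while the keratin gene KRT19 rose 1.72-fold. CDH1 stayed bright in NSC, with a mean log2 intensity of 11.57. The members of this list lay higher in NSC replicate 5 than in the other NSC arrays, by a median of 0.90 on the log2 scale. CDH2, the N-cadherin gene typical of neuroepithelium, rose 7.01-fold (2.81 ± 0.12 SE, limma adjusted p = 3.09e-11).

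**Figure D2:**
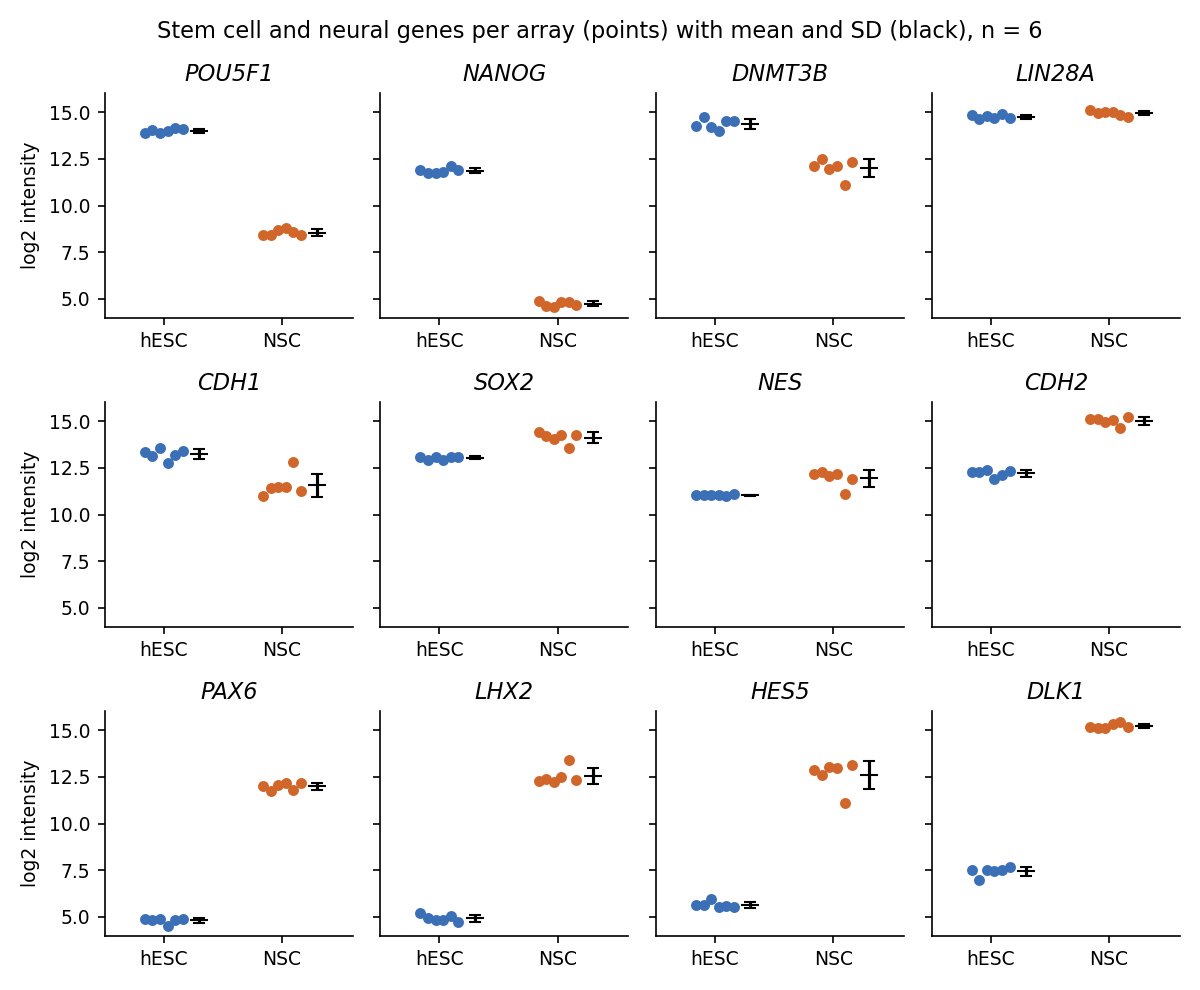
Log2 intensity (vertical axis) of 12 genes on each of 6 hESC arrays (blue) and 6 NSC arrays (orange), with the group mean and SD as black bars. POU5F1 and NANOG are lower on all NSC arrays, PAX6, LHX2, HES5 and DLK1 are higher on all of them, and LIN28A differs by 0.20.

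Neural stem cell and rosette markers rose for 20 of 23 measured genes, and 1, PROM1, fell (median 3.09, or 3.06 with genes below background at their bounds and 1.96 over genes detected on all arrays; camera adjusted p = 4.98e-12, and 0.00326 with an estimated correlation). HES5, a Notch effector of neural progenitors, was 125-fold higher in NSC, or 98.5-fold with each array at no less than its lowest detected signal, and was detected on 1 of the 6 hESC arrays (6.97 ± 0.27 SE, limma adjusted p = 9.59e-12). NES, the gene of the intermediate filament nestin, rose 1.87-fold (0.90 ± 0.17 SE, limma adjusted p = 0.000257), from a mean log2 intensity of 11.04 in hESC. In NSC replicate 5 NES stood at 11.08, the level of the highest hESC array (11.08), against 11.89 to 12.28 in the other NSC arrays. The probe of SOX1 was above background on 0 of the 12 arrays and gave no value.

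Transcription factors of the forebrain rose for all 13 measured members of 19 with a named probe (median 4.50, or 3.16 with genes below background at their bounds). The camera adjusted p was 7.18e-10, and 0.000748 with an estimated correlation. Most of the 13, such as SIX3, RAX and FEZF1, were above background on no hESC array. Such genes could pass the detection filter only through NSC, so the filter itself favours rises in this list. Members below the filter, such as NKX2-1 and TBR1, were above background on no array of either group. Of 22 genes of midbrain and hindbrain patterning with a named probe, 8 were above the detection filter, and all 8 rose (median 2.53, or 0.51 with no detection filter, camera adjusted p = 5.83e-07, and 0.00216 with an estimated correlation). Among them were MEIS2 (at least 14.6-fold higher) and the signalling gene FGF8 (at least 9.80-fold). These and LMX1A were above background on no hESC array and entered only through NSC. Of the members below the filter, EN1, EN2, PAX5 and GBX2 were above background on no array of either group. WNT1 and BARHL1 were each above background on 5 NSC arrays and no hESC array. The rise of the 8 is therefore not a measure of the whole list. Of 29 HOX genes with a named probe, which mark positions from the hindbrain backwards, 2 were measured and neither passed in limma, also at an unadjusted p below 0.05. HOXC13 differed by -0.37 ± 0.22 (SE, limma adjusted p = 0.167), and by -0.54 without hESC replicate 3, when it passed (adjusted p = 0.0269). The forebrain genes lay lower in NSC replicate 5 than in the other NSC arrays, by a median of -0.74 on the log2 scale, although LHX2 itself was highest there.

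Of 22 radial glia and astrocyte markers with a named probe, 12 were measured, and of these 6 rose and 1 fell. The median was 0.47, or 0.20 with no detection filter and 0.79 over genes detected on all arrays (camera adjusted p = 0.0492, adjusted p = 0.114 with an estimated correlation). Of the members below the filter, GFAP, AQP4, S100B, SLC1A2, NFIA and CLU were above background on no array of either group. HOPX was above background on 5 NSC arrays and FAM107A on 4 hESC arrays. The fatty acid binding protein gene FABP7 rose 8.36-fold and NFIB fell 3.97-fold. This list no longer passed without NSC replicate 5 (adjusted p = 0.10), without hESC replicate 3 or 4 (0.052 and 0.0621), without NSC replicate 1 or 6 (0.0504 and 0.0595), or under 4 other alternatives (0.0513 to 0.106). Proneural and young neuron markers went both ways, with 8 of 17 rising and 7 falling (camera adjusted p = 0.629). TAGLN3 rose 7.47-fold and the neurofilament gene NEFM fell 6.05-fold. Of 13 oligodendrocyte lineage markers with a named probe, 4 were measured. SOX10 rose 3.15-fold and PDGFRA was at least 2.17-fold higher in NSC, while MBP (5.08-fold, or 2.69-fold as the mean of its detected probes) and UGT8 (-1.61 on the log2 scale) fell, so that the median was 0.02, or -0.25 with PDGFRA at its bound, and the mean -0.12.

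Neural crest markers rose for 10 of 15 measured genes and fell for 5. Of the 18 genes listed, 3 were also on another list, namely SOX10, FOXD3 and RXRG, which was not measured. The median was 1.57, or 0.78 with genes below background at their bounds and 0.70 without background correction (camera adjusted p = 0.0388, adjusted p = 0.174 with an estimated correlation). MSX1, a factor of the dorsal neural border, rose 14.9-fold and the endothelin receptor gene EDNRB fell 14.3-fold. The call was lost without NSC replicate 5 (adjusted p = 0.0519) and under 4 other alternatives (0.0518 to 0.0857). Over genes detected on all arrays the median was -0.77 (camera adjusted p = 0.392), as that filter removes genes below background in hESC.

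WNT targets and feedback genes rose for 16 of 22 measured members and fell for 3 (4 adjusted over the list alone), with a median of 1.38, or 1.37 with genes below background at their bounds (camera adjusted p = 5.4e-05, adjusted p = 0.114 with an estimated correlation). The receptor gene TNFRSF19 rose 41.1-fold, with 5 of the 6 hESC arrays above background, beside FRZB and DKK1. The 3 that fell were TCF7L1 (2.14-fold), a transcriptional repressor of WNT targets, NKD2 (-0.53 on the log2 scale) and TCF7L2 (-0.42). These genes lay lower in NSC replicate 5 by a median of -0.68. Notch pathway genes rose for 11 of 19 and fell for 3 (HEY2, DLL3 and HES6), with a median of 0.56 (camera adjusted p = 0.0192, adjusted p = 0.114 with an estimated correlation, and 0.0881 over genes detected on all arrays). Hedgehog pathway genes rose for 5 of 7, led by the co-receptor gene GAS1 (18.8-fold), while the target gene GLI1 was detected on 1 of the 6 NSC arrays and fell 4.54-fold, or 2.88-fold with each array at no less than its lowest detected signal. The median of that list was 1.02, or 0.63 without background correction and 0.24 with no detection filter (camera adjusted p = 0.0112, adjusted p = 0.126 with an estimated correlation).

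The NODAL, BMP and TGF-beta list split evenly, with 9 of 20 rising and 9 falling (10 and 10 adjusted over the list alone). BMP2, detected on 4 of the 6 hESC arrays, rose 16.8-fold, and LEFTY1 fell. The median was 0.03, the mean -0.43, and camera pointed down without passing (adjusted p = 0.719). FGF and ERK feedback genes fell for 11 of 22 and rose for 4 (5 adjusted over the list alone), with SPRY4 and FGF8 at the extremes and FGFR3, FGF17 and EGR1 as the other 3 that rose. The camera adjusted p was 0.0855, and 0.0209 without NSC replicate 5, where these genes lay higher by a median of 0.80. It also passed under 3 other alternatives (0.0121 to 0.0368). Retinoic acid pathway genes rose for 4 of 10 and fell for 4. ALDH1A2, which makes retinoic acid and was detected on 3 of the 6 hESC arrays, rose 12.7-fold and the retinal reductase gene DHRS3 fell 7.49-fold. The median was 0.01, the mean -0.09, and camera did not pass (adjusted p = 0.891). Axon guidance ligands and receptors rose for 11 of 19, led by the ephrin receptor gene EPHA4 (76.0-fold), and fell for EFNA1 (1.76-fold) and SEMA6A (-0.33 on the log2 scale). Their median was 0.50 (camera adjusted p = 0.00698, and 0.0393 with an estimated correlation), and the call was lost over genes detected on all arrays (adjusted p = 0.0737).

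**Figure D3:**
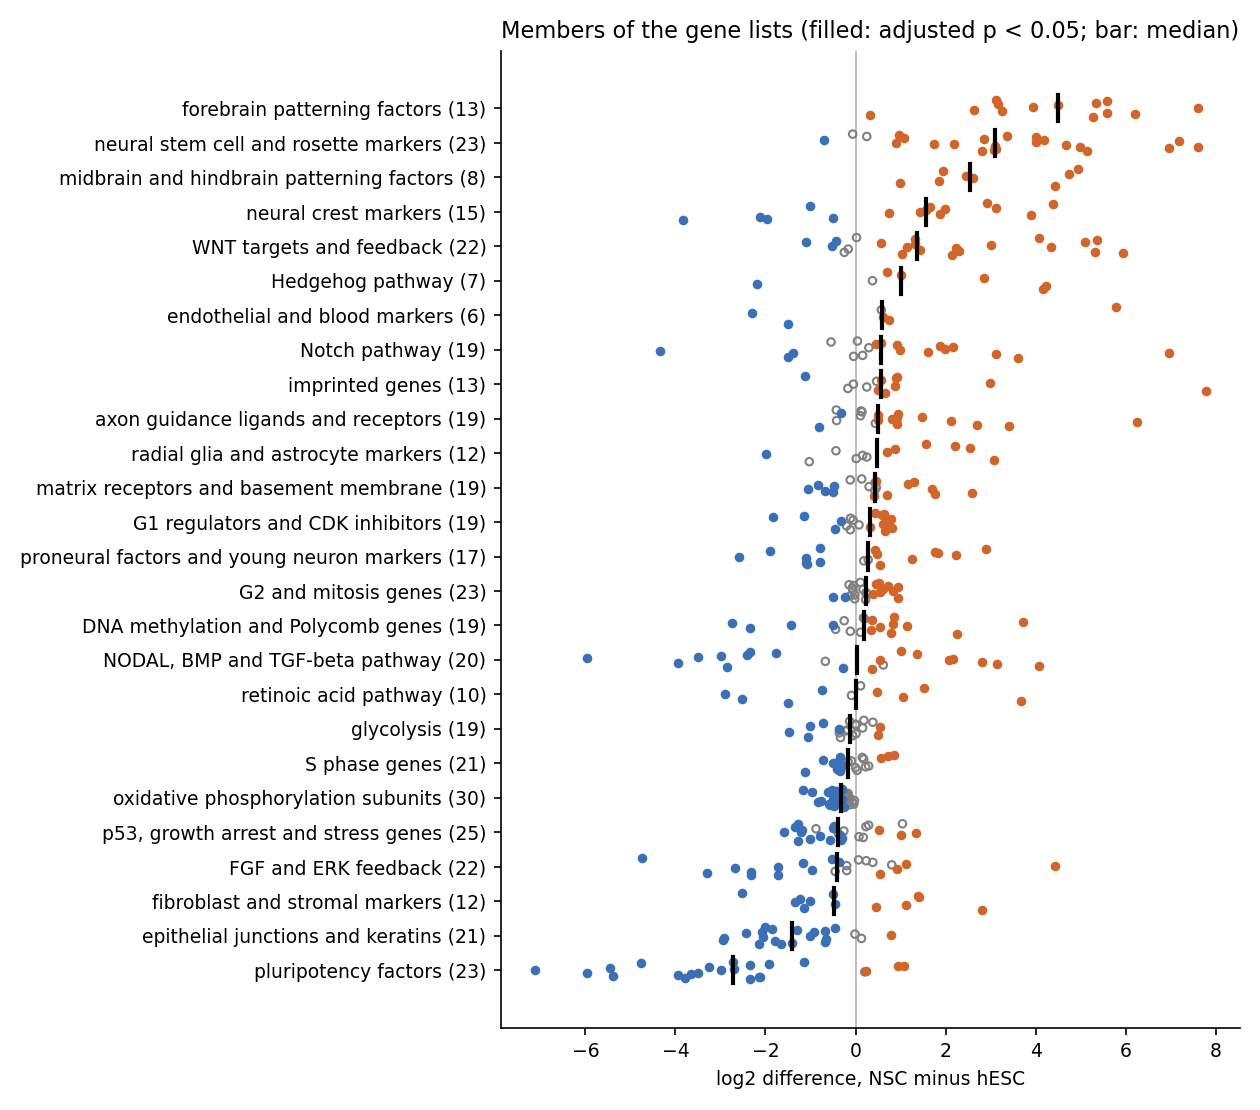
Log2 difference of NSC minus hESC (horizontal axis) of each measured member of the 26 lists with a set test (vertical axis, number measured in brackets). Filled points passed the gene test and open ones did not, black bars are medians, and genes below background in one group are drawn at their fitted difference. The medians run from 4.50 for the forebrain factors to -2.73 for the pluripotency factors.

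Few markers of mesoderm, endoderm, trophoblast and amnion passed the detection filter of 6 arrays. Only 2 of the 17 mesoderm markers with a named probe were measured, of which FOXC2 rose 1.92-fold and KDR was at least 3.13-fold lower in NSC. Of 14 endoderm markers with a named probe 4 were measured, and the chemokine receptor gene CXCR4, which neural precursors also use, was at least 6.63-fold higher in NSC. AFP was at least 2.28-fold lower and FOXA3 differed by -0.90 on the log2 scale (median -0.41, mean 0.21). The 2 trophoblast and amnion markers measured, of 14 with a named probe, were TFAP2C, which rose 1.28-fold, and GABRP. GABRP was detected on 1 of the 6 NSC arrays and fell 2.57-fold, or 1.95-fold with each array at no less than its lowest detected signal. Fibroblast and stromal markers rose for 5 of 12 and fell for 7 (camera adjusted p = 0.864), with the smooth muscle actin gene ACTA2 rising 7.02-fold and THY1 falling 5.73-fold. Of 18 endothelial and blood markers with a named probe, 6 were measured, and of these 3 rose and 2 fell (camera adjusted p = 0.629). Of the members below the filter, PECAM1, CDH5, TIE1, ERG and EMCN were above background on no array of either group. VWF was at least 29.7-fold higher in NSC, the others that rose being CD34 (0.74 on the log2 scale, detected on 2 hESC and 5 NSC arrays) and CD68 (0.62).

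Cell cycle lists did not pass as sets in camera, while fry passed the G2 and mitosis list and the G1 list (fry adjusted p = 3.38e-05 and 0.0194). S phase genes fell for 8 of 21 and rose for 3 (camera adjusted p = 0.542), with the cyclin gene CCNE1 falling 2.18-fold and UHRF1 rising 1.82-fold. G2 and mitosis genes rose for 9 of 23 and fell for BUB1B and BUB1 (1 fell adjusted over the list alone; camera adjusted p = 0.117), and none of these changed 2-fold. BIRC5 rose 1.93-fold and BUB1B fell 1.41-fold. Among G1 regulators and CDK inhibitors, 10 of 19 rose and 4 fell (camera adjusted p = 0.432). MYC fell 3.58-fold and CDK2 rose 1.76-fold.

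Subunits of oxidative phosphorylation fell for 17 of 30 measured genes, by small amounts, and the other 13 did not pass (median -0.31, camera adjusted p = 0.00127, adjusted p = 0.114 with an estimated correlation). SDHD, a subunit of succinate dehydrogenase, fell most, 2.24-fold (-1.16 ± 0.12 SE, limma adjusted p = 9.21e-07). Glycolysis genes fell for 5 of 19 and rose for ENO2 and PFKM (1.47-fold), with the hexokinase gene HK1 falling 2.77-fold (camera adjusted p = 0.432). Without NSC replicate 5, where these genes lay higher by a median of 0.65, 9 fell and 2 rose.

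The p53, growth arrest and stress list fell for 14 of 25 genes and rose for 3 (median -0.38, camera adjusted p = 0.0438, adjusted p = 0.439 with an estimated correlation). The haem oxygenase gene HMOX1 fell 3.01-fold, and the 3 that rose were GADD45A (2.54-fold), DDIT4 (2.0-fold) and HSPA5 (0.51 on the log2 scale). This call was lost without NSC replicate 1 (adjusted p = 0.0504) or 6 (0.0649), and under 3 other alternatives (0.0509 to 0.0531). Imprinted genes rose for 8 of 13 measured, led by DLK1 and its neighbour MEG3 (at least 3.70-fold), and SNRPN fell 2.18-fold (median 0.56, or 0.37 with no detection filter, camera adjusted p = 0.0209, adjusted p = 0.103 with an estimated correlation). DNA methylation and Polycomb genes rose for 9 of 19 and fell for 4 (camera adjusted p = 0.374), with the related genes PHC2 and PHC1 at opposite ends, up 13.2-fold, with 4 of the 6 hESC arrays above background, and down 6.72-fold. Matrix receptors and basement membrane genes rose for 8 of 19 (9 adjusted over the list alone) and fell for 5 (camera adjusted p = 0.138). The collagen IV gene COL4A6 rose 6.01-fold and the integrin gene ITGA6 fell 2.09-fold.

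Of the 26 lists tested, 14 passed with camera's preset correlation, 10 of them higher and 4 lower in NSC. With an estimated correlation 5 held, namely pluripotency factors, neural stem cell markers, both sets of patterning factors and axon guidance genes. Where no other count is given, the counts adjusted over the list alone equalled those over all genes tested. Fry, which asks whether a list's genes moved one way on balance without comparing them with other genes, passed 23 lists.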

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

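The tests of a dim array, of the source of the higher hESC genes and of HIF targets on no gene list in NSC replicate 5 were chosen after the result was seen. In 141 sets of 6 arrays, 1 array's gap to its nearest neighbour was compared with the whole range of the set, and 38 sets had an array too far out. Chance gives about 1 in 20. NSC replicate 5 was that array in 27 of them.

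The mean correlation of NSC replicate 5 with the other NSC arrays was 0.952, against 0.981 to 0.985 for the others, a gap of 0.875 of the range. It was lowest among NSC for the WNT-related genes DKK1 (0.866 of the range) and TNFRSF19 (0.906), and for HES5 (0.739), NES (0.679), MSX1 (0.775), ZNF503 (0.897), CNTFR (0.843), IGFBP5 (0.803), PRSS23 (0.686), CXCR4 (0.643), ALDH1A2 (0.679), UHRF1 (0.843) and COL4A6 (0.724). It was highest for the epithelial genes CDH1 (0.725), KRT19 (0.891) and CLDN7 (0.65), for LHX2 (0.769), FGF8 (0.878), FABP7 (0.77), MYC (0.795), GADD45A (0.812), MBP (0.818), EDNRB (0.682), FOXC2 (0.636), EFNA1 (0.675) and UCA1 (0.722). CDH1 stood at 12.79 in it and at 11.01 to 11.50 in the other NSC arrays, and GADD45A at 12.51 against 10.26 to 10.68.

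Over all genes, those farthest above the other NSC arrays in NSC replicate 5 were the metallothionein gene MT1X (3.98 on the log2 scale), the angiogenic growth factor gene VEGFA (3.31) and ADM (3.29). The farthest below were POU4F1 (-3.98), EHBP1-AS1 (-3.94) and NRIP3 (-3.59), and DKK1 (-3.12) was low too, while DLX5 (2.72) and NEUROG2 (2.67) were high.

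For NSC replicate 5, noise in weak signals alone does not account for the pattern. Among the 3204 brightest genes the SD of its deviations was 3.12 times the median of the other NSC arrays. A technical fault that also alters bright signals cannot be told apart by this test. The 95th percentile of its raw intensities, 2870, was the lowest of all arrays, the next being 2968 in NSC replicate 2. Embryonic stem cells left in that sample are argued against as the source of its higher hESC genes. The 141 such genes would need a median share of 31.7% of the hESC signal (quartiles 17.8% and 49.3%), whereas 199 genes seen on all hESC arrays and on no other NSC array carried a median of -1.2% (quartiles -10.1% and 6.38%), and NANOG was not above background. The shares were taken from intensities before normalization. The 141 genes were picked for being at least 2-fold higher in this array than in the other NSC arrays, so a high share was built in for them. In the other NSC arrays the median share over the 199 genes ran from -9.09% to 7.25%. A small share of embryonic stem cells cannot be told apart from none, since 10.6% of the 199 genes were detected, within the 1.66% to 12.7% of the other NSC arrays. A low-oxygen response in that sample may account for part of the pattern, as a hypothesis. It was set after some genes of this array had been looked at. Of 22 HIF targets, 19 lay above the other NSC arrays, by a median of 0.66 at percentile 99.99 of 10000 matched random lists. Since 7 of the 22 were also on a gene list, the other 15 were tested alone (12 above, median 0.64, percentile 99.94). The matched lists ignore correlation between targets, and all these values come from 1 array. Another shift that these genes share cannot be told apart by this test, and a shift in regional identity was not tested.

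In hESC, replicate 4 was the array farthest out for GAL (0.747 of the range), RARRES2 (0.728), KRT19 (0.638), NFIB (0.79), GABRP (0.77), GLI1 (0.633) and BIRC5 (0.638). Replicate 2 was farthest out for DLK1 (0.698) and TCF7L1 (0.846), replicate 3 for HEY2 (0.728) and replicate 1 for CCNE1 (0.683).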

How the results depend on the processing

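The list counts without NSC replicate 5 were chosen after the data were seen, and all other alternatives before. The count of genes past the threshold, 6906, lay between 5720 and 7999 under the alternatives on single genes, with 48.3% to 51.8% of calls higher in NSC and 81.6% to 99.2% of the 6906 calls shared. Testing each probe on its own gave 10470 calls among more tests. With 1 array left out in turn, it lay between 6513 and 7659, highest without NSC replicate 5. The replicate block gave 6756 genes, 2147 by at least 2-fold and 13 lists. Same-numbered samples showed little sign of deviating together, with correlations from -0.097 to 0.127 (1 of 6 pairs over 0.1). Of 6 samples, 2 correlated best with their own number. The numbers are not read as pairs, though these values cannot exclude pairing. The block ended the call of the radial glia list (adjusted p = 0.0587) and changed no other call of a list or named gene.

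The count of genes changed at least 2-fold, 2146, was 1306 without background correction and 1313 in the authors' table, where the background left in the signal compresses folds. It was 1359 among genes detected on all arrays, a filter that removes genes below background in one group, and 1159 in the test against a 2-fold change. It lay between 2089 and 2201 with 1 array left out. The 14 lists were 9 over genes detected on all arrays, 5 with an estimated correlation, 23 with fry and 12 to 14 with 1 array left out. The mean correlation of hESC with NSC arrays, 0.885, was 0.949 with no detection filter and 0.907 without background correction; the cause was not tested.

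Named genes kept their direction and side of the threshold in 1850 comparisons with an alternative, and in 8 LIN28A (7) or HOXC13 (1) passed the threshold. Lists did so in 569, lost the call in 21, gained it in 4 (FGF and ERK feedback) and turned in 1, a tally without the other set tests, where 9 lists lost the call with an estimated correlation and 9 gained it with fry. The list that turned was neural crest over genes detected on all arrays, at -0.77 (adjusted p = 0.392, and 0.024 to 0.392 over its alternatives), through the same filter. For the other changed list calls, the cause was not tested. Slide as a block was not run, as no slide was given in the sources used here. Signal over background limits the dim genes, of which 145 and 173 have only a bound on their fold.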

Other observations

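The families of genes that share the start of their symbol and the unadjusted counts of the splits were tested after the data were seen, and the other tests in this part were set down before their results were seen. Of 128 such families with at least 10 genes tested, 12 passed with camera's preset correlation, 5 higher and 7 lower in NSC. With an estimated correlation camera passed 0 of the 128 (8 at an unadjusted p below 0.05), and fry passed 83. Under 4 other scalings of the arrays, none of the medians of the 12 families changed sign, but 3 moved by over 1.5 times, all without background correction and in the authors' table. Claudin genes, which form tight junctions, fell for 9 of 12 (median -1.36, or -0.86 without background correction, adjusted p = 0.00909, adjusted p = 0.591 with an estimated correlation). HSPA genes, which encode heat shock chaperones, fell for 10 of 13 and rose for 2 (median -0.95, adjusted p = 0.00909, adjusted p = 0.498 with an estimated correlation). Protocadherin beta genes, which mediate neuronal cell adhesion, rose for 9 of 12 (median 1.17, or 0.68 without background correction, adjusted p = 0.012, adjusted p = 0.711 with an estimated correlation), though they are near-copies of each other and their probes can share signal. Intraflagellar transport genes, which build cilia, rose for 12 of 17 (median 0.59, adjusted p = 0.022, adjusted p = 0.591 with an estimated correlation). SOX genes rose for 8 of 12 and fell for 1 (median 1.21, adjusted p = 0.022, adjusted p = 0.591 with an estimated correlation), and ZNF genes rose for 145 of 358 and fell for 58 (median 0.25, adjusted p = 0.0316, adjusted p = 0.711 with an estimated correlation).

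UTP genes, which act in making ribosomal RNA, fell for 8 of 10 (median -0.70, adjusted p = 0.0437, adjusted p = 0.591 with an estimated correlation), and PSMB genes of the proteasome core fell for 8 of 10 (median -0.49, adjusted p = 0.022, adjusted p = 0.711 with an estimated correlation). Among probes without a gene name here, 3630 passed the detection filter and 1729 of them passed the test as single probes, 190 at least 2-fold higher and 224 at least 2-fold lower in NSC.

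For the lower oxidative phosphorylation subunits in NSC, a fall shared by all genes of like brightness is argued against. Only 0.2% of 10000 random lists matched on mean expression had a median as low as -0.31 (their own median was -0.003). This test was set down for compression of bright probes, but it cannot decide on that, since compression shrinks differences in both directions. With an estimated correlation, camera gave an adjusted p of 0.114 for the subunits. NSC replicate 5 alone is argued against as well, since 21 of the subunits fell without it. A lower level of nuclear genes of mitochondria in general stays open as a hypothesis and may include these subunits. Mitochondrial ribosomal protein genes fell for 54 of 78 and rose for 3, and their median of -0.47 lay at percentile 0 of 10000 matched lists. Such lists ignore correlation between members, and with an estimated correlation camera gave an adjusted p of 0.711 for the large and for the small ribosomal subunit. The wider families of symbols starting with NDUFA (1 rose, 4 fell), NDUFB (1 rose, 3 fell) and COX (3 rose, 8 fell) did not pass with the preset correlation (camera adjusted p = 0.725, 0.377 and 0.581). Whether culture conditions differed between the groups is not given in the sources used here, and no such difference was tested.

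Splits of the 12 arrays into 6 and 6 were compared with the real one in 100 of 462 possible splits. As many genes were reached in 1 of the 100 splits, the real one, with 6906 genes against 0 in any other by limma's adjusted p (7360 against at most 4491 at an unadjusted p below 0.05, with a median of 177). The same held for genes changed at least 2-fold (1 of 100, 2146 against 0, or 2148 against at most 1130 at an unadjusted p below 0.05) and for lists (1 of 100, 14 against at most 12). The real split thus ranked first of the 100 in all 3 counts. Any other split puts both cell types into each group, which widens the spread within groups and lowers the adjusted gene counts. For lists the gap was small, so chance is not excluded for that count. Other splits reached a median of 6 lists, so a list's call with the preset correlation alone is weak evidence.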
